A study of Mus musculus with 123 samples.

How the data were processed

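Messenger RNA (RNA-seq) and open chromatin (ATAC-seq) were measured in the cortex of the same male C57BL/6J mice, per the labels. Mice were kept awake by gentle handling for 6 h from light onset, and undisturbed controls were sampled at ZT0, ZT3, ZT6, ZT12 and ZT18. The ZT0 controls carry the labels T0 and T24, 4 animals each, and were treated as 1 group of 8 for comparisons, since both are undisturbed mice at light onset. RNA libraries came from stranded, poly(A)-selected RNA read as single-end reads on an Illumina sequencer, with more than 36 M (median 55 M) mappable reads per the labels' protocols. ATAC libraries came from isolated nuclei and gave more than 25 M (median 41 M) mappable paired-end 50 bp reads after duplicate and mitochondrial reads were removed, per the labels' protocols. The labels of T36 samples place them during deprivation, while the protocol ends deprivation 6 h earlier; the protocol's time was used.

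The authors quantified the data with FastQC, kallisto 0.43.0, sleuth 0.29.0, Bowtie2, SAMtools, bedtools 2.26.0, MACS2 2.1.1 and HTSeq 0.6.1 on mouse genome builds GRCm38 and mm10, per the submitters' processing notes, which give neither their order nor their settings. The versions of FastQC, Bowtie2 and SAMtools are not given in the sources used here. The deposited RNA table holds 13842 genes in log2 units, and its values show an offset of 0.5 added to a depth-normalized level. Whether that level was scaled by gene length is not given in the sources used here. Batch had been adjusted by the authors before deposit: a gene at zero lies at exactly -1 in batch 1 (48 values) and never in batch 2, where 23 values lie below -1, down to -3.85. The first column merges both libraries of 1 ZT0 animal, T0N5. They are labelled batch 1 and batch 2, and the merged column was counted as batch 1. The deposited ATAC table holds normalized signal for 130727 peaks in 60 libraries, with column sums between 943538 and 1039380 and no visible batch adjustment. Every value was a whole number of reads (100% of values, tolerance 0.02) times a step of its library, which gave the reads back: 2.21 to 11.9 M per library, with medians of 4.02 M in batch 1 and 6.26 M in batch 2. The repeat ATAC library of 1 ZT0 animal was left out, which left 59. The rule by which peaks of single libraries were joined is not given in the sources used here.

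Each sleep-deprived group was compared with controls of the same time of day in 1 linear model per assay, with a mean for each group and a term for batch (limma 3.58.1 in R 4.3.3, moderated with an intensity trend, 44 residual degrees of freedom for RNA and 41 for ATAC). ATAC signal was taken as log2 of the value plus 0.5, and RNA values were used as deposited. The p-values of each comparison were adjusted over all genes or peaks by the Benjamini-Hochberg method, with calls below 0.05. All tests were two-sided. Time of day in controls and the change of the deprivation effect over Day 2 were tested with limma F-tests, and differences between the effects of neighbouring times as contrasts of contrasts. The ZT0 controls labelled T0 and T24 were compared as a negative control. Fold changes are model estimates with standard errors (SE), while group levels are given as mean and standard deviation (SD) over animals. T66 has 1 ATAC library, which the model assumes to vary like the other groups. Animal numbers do not pair samples across groups: residuals of samples with the same number had a median correlation of -0.0014 in RNA over 330 pairs and -0.0039 in ATAC over 299 pairs.

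Gene and peak names were chosen by a rule. At T27, T30 and T36 the 12 genes with the largest rise and the 12 with the largest fall were named, from those with adjusted p below 0.05, treated and control libraries that did not overlap, and a mean level above the 25th percentile. At later times 5 each way were named, for time of day and Day 2 the 12 with the widest range, and for ATAC 6 peaks each way at T27, T30 and T36 and 3 elsewhere; gene models without a standard name were passed over for RNA. Members of 26 fixed lists were named as well, except some that are not reported here. The lists, with measured over listed genes, were clock 21 of 21, immediate early 22 of 22, MAPK feedback 13 of 14, cytosolic heat shock 20 of 20, ER chaperone and unfolded protein response 22 of 23, cold-inducible 2 of 2, glucocorticoid-responsive 18 of 19, cholesterol biosynthesis 21 of 21, postsynaptic 26 of 26, presynaptic 25 of 25, neuropeptide 13 of 15, cytosolic ribosomal protein 35 of 35, oxidative phosphorylation 34 of 34, and markers of inhibitory neurons 12 of 12, excitatory neurons 12 of 12, astrocytes 13 of 13, oligodendrocytes 12 of 12, their precursors 10 of 10, microglia 13 of 13, endothelium 12 of 12, mural cells 10 of 10, meninges 8 of 10, choroid plexus 3 of 10, blood 6 of 8, striatum 9 of 11, and thalamus or hippocampus 7 of 9. Some genes sit in 2 lists: Per1 (clock and glucocorticoid), Dusp1 and Errfi1 (MAPK and glucocorticoid), Gjb6 (glucocorticoid and astrocyte), and Rora, Rorb, Slc32a1, Slc17a7, Sst, Vip, Tac1, Penk and Cspg4. Every measured member is in the table of cortex genes, so the marker lists hold genes that cortex libraries also contain.

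Lists were tested as sets with camera (limma) at a preset correlation of 0.01, adjusted over the 26 lists within a comparison, and again with the correlation estimated from the residuals. Adjusted p of sets given for T27, T30, T36, T42 and later times without further words are from camera. Gene positions and the nearest gene of each peak came from a RefSeq table for GRCm38.p6 without strand (GenomicRanges 1.54.1), so distances run to the gene span and not to the transcription start; 13615 RNA genes had a position. As a check of the coordinates, 13.9% of peaks lay within 500 bp of a gene boundary, against 5.05% after a shift of 100 kb. Of all peaks 86869 had a nearest gene in the RNA table. Nearest genes of called peaks were compared with RNA calls by Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

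Power was tested on simulated data with the group sizes of the real tables. RNA values were drawn with the real spread of each gene, independently across genes, and ATAC reads with 1 spread common to all peaks. Shifts shared by many genes or peaks of a library were not simulated, so recovery and false calls in the real libraries may differ. For RNA comparisons of 3 with 3, 5 and 8 libraries (T27, T30 and T48), limma recovered 42%, 60% and 66% of changes of 0.25 log2 units, 92%, 94% and 96% of changes of 0.5, and 98% or more of changes of 1. False calls were 5, 7 and 8 of 13642 unchanged genes. For ATAC at T30, limma recovered 10% of changes of 0.5, 48% of changes of 1 and 96% of changes of 2 log2 units, and edgeR on reads 8%, 54% and 94%. In this simulation, ATAC changes well under 2-fold were therefore mostly missed at this depth and group size.

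The groups, comparisons, naming rule, lists and most alternatives were fixed before the data were examined. The alternatives were no batch term, the upper 75% of features by mean level, quantile normalization, a block for the animal number, only the libraries of the 2 groups compared, only controls of the same batch, leaving out in turn each deprived library and each control library of groups of 5 or fewer, a pseudocount 10 times smaller or larger and the repeat library included (both ATAC), a 24 h cosine and batch 1 alone for time of day, and estimated correlations for lists. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood, on recovered ATAC reads), the merged RNA column left out, each ZT0 control left out in turn (with each ZT6, ZT12 and ZT18 control for Day 2), marker scores as covariates, and peaks inside genes only. For RNA the repeat library and the pseudocount could not be varied, as the deposited values merge the former and fix the latter. A distance limit to the transcription start was not run, for want of strand. Other splits of the libraries into groups of the same sizes were counted, all of them up to 100 and a random 100 beyond that in RNA, with 30 in later ATAC comparisons and 40 in ATAC F-tests for time.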

Results

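Messenger RNA and open chromatin were measured in the cerebral cortex of adult male C57BL/6J mice, an inbred laboratory strain, before, during and after 6 h of enforced wakefulness. Sleep was prevented by gentle handling from light onset (ZT0, zeitgeber time counting hours after lights on) until ZT6, which on the study's clock ran from 24 h to 30 h. RNA-seq counts transcripts, and ATAC-seq uses a transposase that inserts adapters into accessible DNA, so that read density marks open chromatin. Undisturbed controls with an RNA library comprised 8 animals at ZT0, 3 at ZT3 and 5 each at ZT6, ZT12 and ZT18. Each of 12 sleep-deprived groups held 3 animals with an RNA library: T27 and T30 during deprivation (after 3 h and 6 h), and T36 and T42 in the recovery that followed. Groups T48, T54, T60 and T66 were taken on Day 2, T72 and T78 on Day 3, and T192 and T198 about 1 week after deprivation (Day 8). Every sleep-deprived group was compared with undisturbed controls of the same time of day.

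RNA values covered 13842 genes in 62 animals, and ATAC values covered 130727 peaks (regions of open chromatin, median width 546 bp) in 59 animals. ATAC-seq group sizes were the same except at ZT18, with 4 controls, and at T66, with 1 animal. Between 2.21 M and 11.9 M reads lay in peaks per ATAC library (median 4.09 M), and the T66 library was the deepest. RNA library depth cannot be read from the values; the labels state more than 36 M mappable reads per library. Libraries carried labels of 2 batches. T60, T66, T192 and T198 belonged wholly to batch 2 and the other deprived groups to batch 1. Controls of both batches were present at each time but ZT3. ZT0 animals T0N3 and T0N5 were labelled batch 1 but their repeat libraries batch 2, so the label does not follow the animal alone. Below, the batch of an animal is that of its first library.

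Time of day alone changed much of the cortical transcriptome. In undisturbed controls 5630 of 13842 genes (40.7%) differed between times of day (limma F-test, adjusted p below 0.05). Dbp, a clock-driven transcription factor gene, was highest at ZT12 at 7.02 ± 0.08 (log2 units, SD, n = 5) and lowest at ZT0 at 5.39 ± 0.19 (SD, n = 8), a 3.09-fold difference (adjusted p = 6.04e-18). Its span is chromosome 7, 45705100 to 45710203, on GRCm38. Ciart, which encodes a repressor of the clock, ranged over 1.95 log2 units with its high at ZT12 and its low at ZT0 (adjusted p = 3.22e-14), and Per2, a core clock repressor gene, over 1.48 log2 units between ZT18 and ZT3 (adjusted p = 2.98e-12). More genes were highest at ZT18 (1696) than at ZT12 (1121), ZT6 (1115), ZT0 (975) or ZT3 (723).

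Arc, whose protein acts in synaptic plasticity and whose transcript follows neuronal activity, averaged 7.80 ± 0.57 at ZT0 (SD, n = 8) and 5.18 ± 0.95 at ZT6 (SD, n = 5), a range of 2.61 log2 units (adjusted p = 0.000356). Fos (1.75 log2 units), Egr1 (1.44), Nr4a1 (1.40) and Egr3 (1.25), transcription factor genes of the same class, and Tnfrsf25 (1.51), a death-domain receptor gene, also varied with time of day. The small heat shock protein gene Hspb1 ranged over 1.32, Trib1, a pseudokinase gene, over 1.30, and Erdr1 over 1.51 log2 units, the last with a weak call (adjusted p = 0.0325).

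Between ZT6, when mice mostly sleep, and ZT18, in their active phase, many members of several gene lists differed, although none of the 9 lists called as sets with a preset correlation held with an estimated one. At ZT18, 15 of 22 measured genes for chaperones of the endoplasmic reticulum (ER) and the unfolded protein response were higher, among them Sdf2l1 (1.22 log2 units) and Hspa5 (0.85), which encodes the main ER chaperone BiP. Higher too were 13 of 20 cytosolic heat shock genes (Hspa1b by 1.24) and 14 of 22 immediate early genes (Egr2 by 1.58, Fos by 1.13). Lower at ZT18 were 17 of 21 cholesterol biosynthesis genes, with Insig1 at -0.71 and Hmgcs1 at -0.52, and both cold-inducible RNA-binding protein genes, with Cirbp at -0.73. Adjusted over the list alone, the counts were 16 higher and 1 lower for the ER list, 14 higher for heat shock, 16 higher for immediate early and 17 lower with 1 higher for cholesterol genes. As sets, with an estimated correlation, the lists had adjusted p = 0.117 for ER, heat shock and cold-inducible genes, adjusted p = 0.185 for cholesterol genes and adjusted p = 0.327 for immediate early genes. Within batch 1 alone, time of day changed 2949 genes.

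Sleep deprivation for 3 h (T27 against ZT3) raised 1136 genes and lowered 1020, together 15.6% of those tested, and of these 43 changed by more than 1 log2 unit. Arc (chromosome 15, 74669081 to 74672570) rose 4.29-fold, from 6.39 ± 0.88 to 8.49 ± 0.21 (SD, n = 3 each; SE of the log2 change 0.71, adjusted p = 0.0361), and Tnfrsf25 rose 3.76-fold (log2 change 1.91, SE 0.30, adjusted p = 9.79e-06). Pla2g4e, a cytosolic phospholipase gene (chromosome 2, 120166412 to 120245630), fell from 3.79 ± 0.01 to 2.45 ± 0.11 (SD, n = 3 each; log2 change -1.34, SE 0.19, adjusted p = 1.53e-06). The cell cycle inhibitor gene Cdkn1a rose by 1.49 log2 units (SE 0.18, adjusted p = 1.84e-07) and Per2 by 1.35 (SE 0.18, adjusted p = 1.30e-06).

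Of 22 immediate early genes 17 rose at T27, Egr2 by 2.66 log2 units, Fosb by 1.97, Fos by 1.73, Nr4a3 by 1.71, Sik1 by 1.66, Egr1 by 1.25, and Nr4a1 and Fosl2 by less. Jun fell by 0.45 (19 higher and 1 lower adjusted over the list alone). Of 13 regulators that dampen MAPK signalling 9 rose, with Dusp4 at 1.47 and Dusp5 at 1.30, and Dusp8 fell (10 and 1 adjusted over the list alone). ER chaperone and unfolded protein response genes rose in 14 of 22 cases, including Sdf2l1 (1.14), Hspa5 (0.81), Pdia4 (0.69) and Xbp1 (0.62). Cytosolic heat shock genes rose in 8 of 20, including Dnajb5 (1.11) and Hspb1 (0.87); 17 and 12 rose adjusted over the list alone. Glucocorticoid-responsive genes rose in 9 of 18 cases (10 adjusted over the list alone), among them Per1 (0.89) and Tsc22d3 (0.57). Each of these 5 lists moved as a set with an estimated correlation too (adjusted p = 0.0320 for all but heat shock, at adjusted p = 0.0458).

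Other rises at T27 included those of Trib1 (1.26 log2 units) and Stac3 (1.21). Other falls included those of Hunk (-1.03), a kinase gene, Pcdh20 (-0.93), a protocadherin gene, Sh2d3c (-0.73), Ankrd34c (-0.71), Zfp46 (-0.70) and Dcx (-0.70), a microtubule-binding protein gene of migrating neurons. Smaller falls were those of Dact2 (-0.69), Zc3h6 (-0.68), Prr16 (-0.63), Zkscan2 (-0.61) and Fbxl4 (-0.59). Among 21 clock genes 5 rose, including Bhlhe40 (0.90) and Cry1 (0.47), and 2 fell, Dbp (-0.40) and Rorb (-0.33), with 6 and 3 adjusted over the list alone; as a set they did not pass (adjusted p = 0.0697). Neuropeptide genes rose in 3 of 13 cases, Vgf (0.59), Crh (0.58) and Scg2 (0.41), but the list was not called with an estimated correlation (adjusted p = 0.135 with an estimated correlation). Cirbp fell by 0.53 log2 units, and with Rbm3 formed a list lost in the same way (adjusted p = 0.127 with an estimated correlation).

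Markers of tissue next to the cortex moved at T27 as well. All 3 measured choroid plexus markers were lower (Ttr at -3.22 with SE 0.78, Kl at -0.41, Enpp2 at -0.27; set adjusted p = 0.0458 with an estimated correlation). Ttr stood at 7.54, 4.66 and 2.95 log2 units in the 3 ZT3 controls and at most 5.04 in any library of another time. Meningeal markers Slc6a13 (-0.49) and Slc13a4 (-0.54) were lower too, with 7 of 8 lower adjusted over the list alone (adjusted p = 0.457 with an estimated correlation). The calls of Arc, Fos and Nr4a1 at T27 were each lost when ZT3 library T3N2 or T3N4 was left out, and that of Ttr without T3N2.

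After 6 h of deprivation (T30 against ZT6) the response had its highest count of changed genes: 2217 rose and 2155 fell, 31.6% of those tested, 70 of them by more than 1 log2 unit. Arc stood 9.69-fold above controls, at 8.43 ± 0.19 (SD, n = 3) against 5.18 ± 0.95 (SD, n = 5; log2 change 3.28, SE 0.66, adjusted p = 0.000119). Fos rose 6.37-fold (log2 change 2.67, SE 0.53, adjusted p = 0.00011). Cirbp (chromosome 10, 80165990 to 80172786), a cold-inducible RNA-binding protein gene, fell from 7.04 ± 0.08 (SD, n = 5) to 6.08 ± 0.09 (SD, n = 3; log2 change -0.97, SE 0.08, adjusted p = 2.14e-12). Dbp fell from 6.56 ± 0.13 to 5.60 ± 0.13 (log2 change -0.96, SE 0.13, adjusted p = 6.95e-08). Against the batch 1 controls alone, the batch of the T30 animals, 3404 genes changed.

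Immediate early genes rose in 21 of 22 cases at T30 (21 also adjusted over the list alone), with Egr2 at 2.85 log2 units, Nr4a1 at 1.97, Junb at 1.85, Fosb at 1.70, Npas4 at 1.46 and Egr1 at 1.42. Rises were also called for 11 of 13 MAPK regulators (12 adjusted over the list alone; Dusp4 1.56, Dusp1 1.53, Dusp5 1.45, Dusp6 1.26) and for 17 of 22 ER chaperone and unfolded protein response genes (17; Sdf2l1 1.39, Pdia4 0.84, Manf 0.79). So were rises of 12 of 20 cytosolic heat shock genes (15; Hspb1 1.37, Dnajb5 1.09) and of 14 of 18 glucocorticoid-responsive genes (14; Plin4 0.93, Sult1a1 0.49, Fkbp5 0.48). Each of these sets was called with an estimated correlation (adjusted p = 0.0286), as was the fall of both cold-inducible genes, Cirbp and Rbm3 (-0.76), at adjusted p = 0.0226.

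Cholesterol biosynthesis genes moved the other way: 15 of 21 fell, including Insig1 (-0.75), Stard4 (-0.43), Sqle (-0.42), Msmo1 (-0.41) and Hmgcs1 (-0.41). Ebp alone rose (0.43), with 16 falls and 1 rise adjusted over the list alone (adjusted p = 0.228 with an estimated correlation). Neuropeptide genes rose in 7 of 13 cases, with Crh at 1.00, Vgf at 0.93, Cort at 0.72 and Scg2 at 0.71 (7 adjusted over the list alone; adjusted p = 0.0916 with an estimated correlation). Of 26 postsynaptic genes 11 rose, the scaffold genes Shank2 (0.48) and Shank1 (0.41) among them, and 3 fell, Dlgap1, Gria4 and Nlgn1 (the same counts adjusted over the list alone; adjusted p = 0.488 with an estimated correlation). Clock genes divided, 9 up and 8 down of 21 (10 and 9 adjusted over the list alone; set adjusted p = 0.691), with Per1 (1.03), Per2 (0.97) and Nfil3 (0.93) higher and Dbp, Ciart (-0.65), Bhlhe41 (-0.52) and Nr1d1 (-0.33) lower.

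Other rises at T30 included those of Tnfrsf25 (2.05 log2 units), Trib1 (1.60) and the synaptic organizer gene Cbln4 (1.39), and other falls those of Pla2g4e (-1.45), Opalin (-0.95), a myelin gene, Zfp46 (-0.84), Sat2 (-0.82), Hunk (-0.78), Adam33 (-0.76), Cln6 (-0.75) and Rccd1 (-0.74). Cell type markers moved little as sets. Oligodendrocyte markers fell in 4 of 12 cases (Opalin, Aspa -0.50, Mog -0.38, Cnp -0.22; set adjusted p = 0.0504), and microglia markers in 4 of 13, with Trem2 at -0.51 and P2ry12 at -0.31, while Tmem119 rose by 0.30 (set adjusted p = 0.374). Counts higher and lower were 3 and 1 of 12 for endothelial markers (Slc2a1 0.32, Slco1a4 -0.41), 0 and 1 of 10 for mural and 1 and 1 of 13 for astrocyte markers. They were 2 and 1 of 10 for oligodendrocyte precursor, 3 and 0 of 12 for inhibitory and 1 and 1 of 12 for excitatory neuron markers. Striatal markers gave 1 and 1 of 9 (Pde10a 0.69, Drd1 -0.32), choroid plexus markers 0 and 1 of 3, and none was called among meningeal, blood and thalamic or hippocampal markers. Presynaptic genes gave 4 and 2 of 25 (Unc13a 0.28, Syt1 -0.19), cytosolic ribosomal protein genes 0 and 1 of 35 and oxidative phosphorylation genes 2 and 3 of 34, and none of these sets was called.

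**Figure D1:**
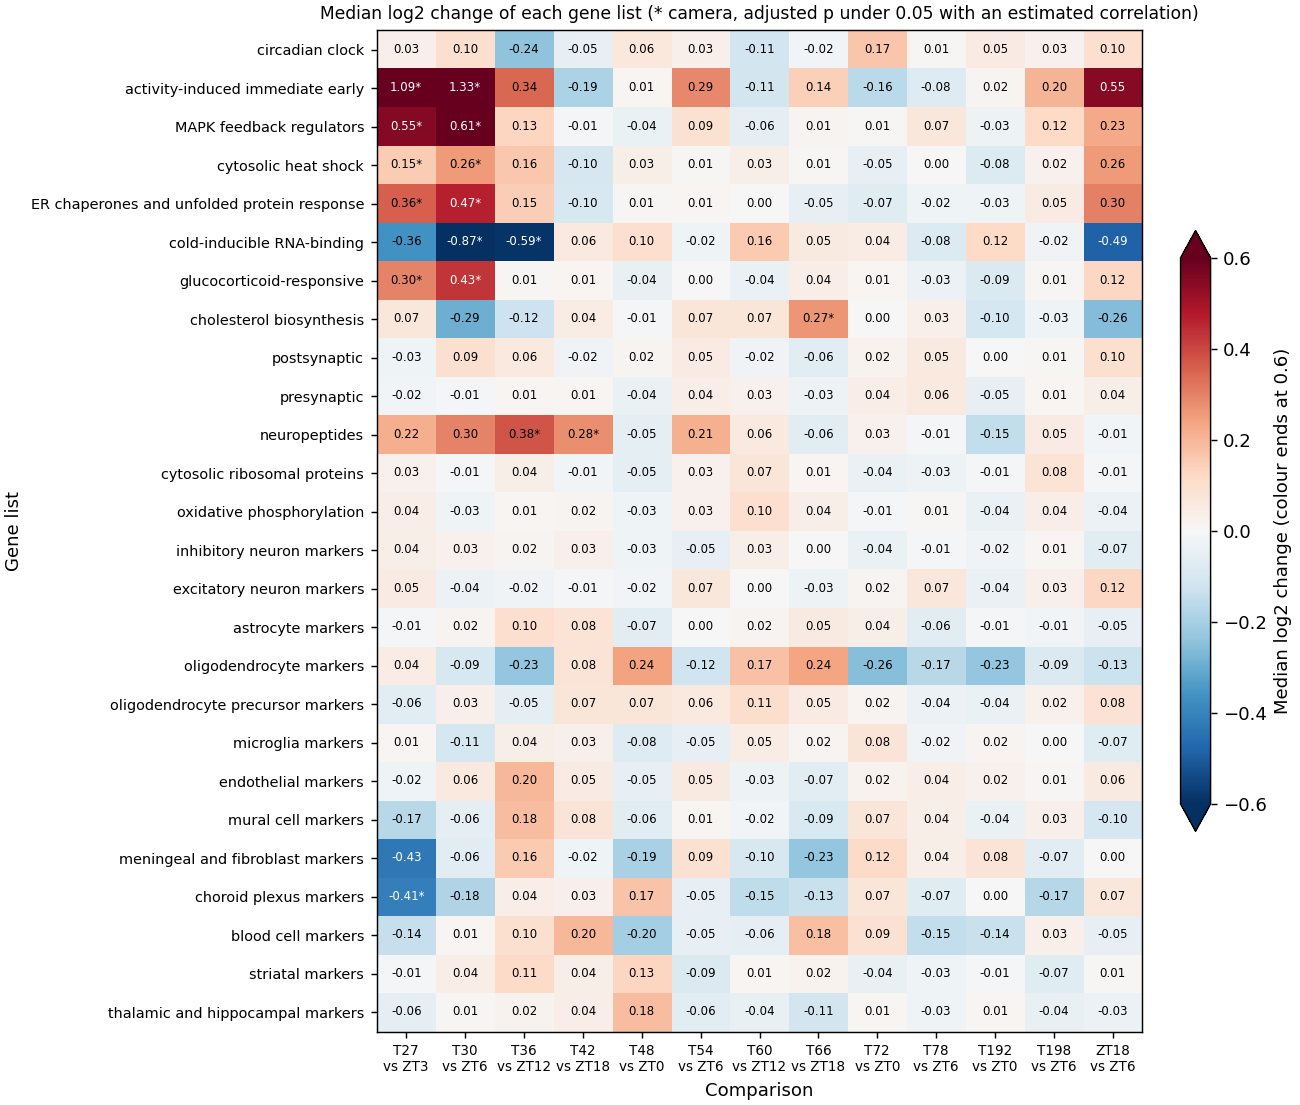
Median log2 change (colour and printed value) of the measured genes of each list, one per line, in each of the 12 comparisons of sleep-deprived animals with controls of the same time of day and, in the last column, for ZT18 against ZT6 in controls; colours end at 0.6 either way, and an asterisk marks a set called with an estimated correlation (camera, adjusted p below 0.05). Immediate early genes stood at 1.09 at T27 and 1.33 at T30, and cholesterol genes at -0.29 at T30 and 0.27 at T66.

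The responses at 3 h and 6 h had many called genes in common. Genes higher at both numbered 911, where independent lists of those sizes would share 182, and genes lower at both 752, where 159 would be shared; the comparisons have no library in common. A test of the difference between the T30 and T27 changes called 1 gene, Sorcs3, a sorting receptor gene of neurons, which stood at -0.16 at T27 and 0.45 at T30 (difference 0.61, SE 0.10, adjusted p = 0.00267); it was chosen after its values were seen.

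Genes that deprivation raised tended to be genes that were higher at ZT18 than at ZT6 in undisturbed mice. Of the 1136 genes higher at T27, 1015 (89.3%) were higher at ZT18 than at ZT6, against 49.1% of all genes, and of the 1020 lower genes 102 (10.0%). Across genes, which are not independent replicates, the T27 change correlated with the ZT18 minus ZT6 difference (Pearson r = 0.521, Spearman rho = 0.513), with no library in common; with the difference taken within batch 1 or batch 2 controls alone, r was 0.487 and 0.420. For T30, whose comparison uses ZT6 controls as well, the controls were divided by batch so that none was shared, and r was 0.484 (rho = 0.546). With all libraries, no batch term and the shared controls left in, r was 0.753, where unchanged groups against shared controls gave a simulated r of 0.402; the covariance was 0.0322 against a simulated 0.00336.

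At T36, 6 h after deprivation ended, 1033 genes were higher and 617 lower than at ZT12 (11.9% of those tested), 10 of them by more than 1 log2 unit. Nptx2, a pentraxin that gathers glutamate receptors at synapses (chromosome 5, 144545887 to 144557478), rose 2.63-fold, from 4.25 ± 0.12 (SD, n = 5) to 5.65 ± 0.14 (SD, n = 3; log2 change 1.40, SE 0.14, adjusted p = 1.58e-10). Crh, which encodes corticotropin-releasing hormone, rose 2.30-fold (log2 change 1.20, SE 0.12, adjusted p = 2.04e-10), and Sorcs3 1.87-fold (log2 change 0.91, SE 0.07, adjusted p = 4.77e-14). Ap1g2, an adaptor protein gene, fell from 4.06 ± 0.21 to 3.15 ± 0.07 (log2 change -0.90, SE 0.14, adjusted p = 9.22e-06).

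Neuropeptide genes rose in 8 of 13 cases at T36 (10 adjusted over the list alone): Crh, Scg2 (0.92), Adcyap1 (0.81), Cort (0.65), Vgf (0.65), Vip (0.49), Cck (0.31) and Pdyn (0.26), and the set was called with an estimated correlation (adjusted p = 0.0097). Both cold-inducible genes remained lower, Rbm3 at -0.84 and Cirbp at -0.33 (adjusted p = 0.0101 with an estimated correlation). Immediate early genes rose in 8 of 22 cases (8 adjusted over the list alone), Nptx2, Egr3 (1.11), Bdnf (1.03), Fosl2 (0.74), Fosb (0.66), Crem (0.61), Homer1 (0.50) and Jun (0.47), but not as a set (adjusted p = 0.394 with an estimated correlation). The same p applied to ER genes, 9 of 22 higher (9 adjusted over the list alone) with Calr at 0.54 and Hsp90b1 at 0.46. Heat shock genes rose in 8 of 20 cases, with Dnajb5 at 0.64, Hsph1 at 0.62 and Hspb1 at 0.59, and Dnajb4 fell (13 and 1 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation). Among clock genes Nfil3 (0.82) and Arntl (0.41) were higher and 7 of 21 lower. These were Ciart at -0.84, Dbp at -0.63, Bhlhe41 at -0.61, Tef at -0.40 and Hlf, Per3 and Nr1d2 at -0.33 each (3 and 9 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation).

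Cdkn1a (1.17 log2 units), Cbln4 (0.97), the receptor gene Mas1 (0.96), Pcdh20 (0.92) and Fam19a1 (0.86) were also higher at T36. Other falls included those of Kcnip4 (-0.65), a potassium channel subunit gene, Hrh3 (-0.63), a histamine receptor gene, Rxfp1 (-0.57), Arsg (-0.56) and Fam205c (-0.53), with Amy1 (-0.57) and Trbc2 (-0.56), whose reads may be divided among near-identical copies. Pcdh20 had fallen at T27. Endothelial (3 of 12 higher, Emcn 0.45), mural (2 of 10, Acta2 0.46) and oligodendrocyte markers (2 of 12 lower, Opalin -0.43 and Aspa -0.41) moved in single genes but not as sets (adjusted p = 0.394 with an estimated correlation for each). So did cholesterol genes (1 higher, 2 lower; adjusted p = 0.612 with an estimated correlation) and postsynaptic genes (5 higher, 1 lower; adjusted p = 0.394 with an estimated correlation). The astrocyte gene Gfap rose by 0.55. Library T36S1 stood apart, with Dbp at 5.83 against 6.61 and 6.74 and Ciart at 4.58 against 5.51 and 5.51 in the other libraries; without it 812 genes were called and the calls of Dbp, Ciart, Cirbp, Gfap, Aspa and Hspb1 were lost. Against batch 1 controls alone 1133 genes changed.

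Between T30 and T36 the change from control itself shifted in 1573 genes, 777 upward and 796 downward (test of the difference, adjusted p below 0.05). Of the 2217 genes higher at T30, 526 were higher at T36 as well, where independent lists would share 165, and 41 were lower at T36. Of the 2155 genes lower at T30, 307 were lower at T36, where 96.1 would be shared, and 63 were higher.

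At T42, in the recovery night, 85 genes were higher and 60 lower than at ZT18, with 48 called without T42S6, 75 without T42S2 and 55 without ZT18 library T18N2. Cort, which encodes cortistatin, a neuropeptide of cortical interneurons, rose 1.72-fold (log2 change 0.78, SE 0.16, adjusted p = 0.00874). With Scg2 (0.39) and Npy (0.28) it made 3 of 13 neuropeptide genes called (8 adjusted over the list alone; set adjusted p = 0.0294 with an estimated correlation). Heat shock genes fell in 4 of 20 cases, Hspa1b (-0.68, SE 0.13, adjusted p = 0.00426), Hspa1a (-0.41), Dnajb1 (-0.24) and Dnaja4 (-0.18), where reads may be divided between Hspa1a and Hspa1b (7 lower adjusted over the list alone; adjusted p = 0.253 with an estimated correlation). Lemd1 (0.54), Clec18a (0.53), Hkdc1 (0.45) and Strip2 (0.45) also rose, and Matn2 (-0.51), Spag5 (-0.41), Mgat5b (-0.41) and Cdk2ap2 (-0.40) fell. Against batch 1 controls alone 40 genes changed and the calls of Cort, Strip2, Npy, Hspa1a, Dnajb1 and Dnaja4 were lost.

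At T48, 24 h after deprivation began and at light onset of Day 2, 79 genes were higher and 97 lower than at ZT0. Several clock genes changed: Dbp rose 1.73-fold, from 5.39 ± 0.19 (SD, n = 8) to 6.19 ± 0.12 (SD, n = 3; log2 change 0.79, SE 0.12, adjusted p = 5.34e-05). Ciart rose by 0.70, Bhlhe41 by 0.40, Nr1d1 by 0.39 and Nr1d2 by 0.37 log2 units. Arntl, which encodes BMAL1, was lower at -0.37 (clock genes 6 and 3 adjusted over the list alone; adjusted p = 0.505 with an estimated correlation). Cdkn1a (-0.63), Crh (-0.41), Nptx2 (-0.47) and Pdk4 (-0.35) were lower, as were the astrocyte genes Gja1 (-0.28) and Aldh1l1 (-0.31). Changes were also called for Cabp7 (0.59), Lfng (0.48), Serpina3n (0.40), Etnk2 (-0.63), Ntn5 (-0.61), Robo3 (-0.48) and Igfn1 (-0.45). Fibcd1, a marker of hippocampal field CA1, was higher by 0.91, with 4 of 7 thalamic and hippocampal markers higher adjusted over the list alone (adjusted p = 0.0904 with an estimated correlation). The 12 oligodendrocyte markers had a median of 0.24 (6 higher adjusted over the list alone; adjusted p = 0.505 with an estimated correlation). Against batch 1 controls alone 48 genes changed, Dbp at 0.88 (SE 0.13), and the calls of Nr1d1, Crh, Nptx2, Pdk4, Lfng and Serpina3n were lost. These controls included the merged column of T0N5, which also holds a batch 2 library. Without T48S1, T48S3 or T48S4 the count was 93, 103 or 70, and without ZT0 library T0N2 or T0N5 104 or 109. The calls of Ciart, Bhlhe41, Nr1d1, Cdkn1a, Crh, Nptx2, Pdk4, Serpina3n, Lfng, Ntn5, Gja1 and Aldh1l1 were each lost without at least 1 of the 11 libraries, while those of Dbp and Fibcd1 held in each case.

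Later recovery times held few called genes. At T54 Cort was the single call (0.85 log2 units), at T60 Cryl1, a lambda-crystallin gene (0.31, SE 0.06, adjusted p = 0.0230), and at T72 Dbp (0.63, SE 0.12, adjusted p = 0.0416), a call lost without any 1 of the 3 T72 libraries or of ZT0 libraries T0N1, T0N2, T0N3, T0N5 and J70N1. At T78 and T192 limma called 0 genes, with 838 and 1039 at unadjusted p below 0.05 where chance alone gives about 692 of 13842. At T198 Sowahc was lower (-0.66), a gene chosen after its values were seen. Against controls of their own batch alone, limma called 0 genes at T60, T66, T72 and T198 (1285, 950, 964 and 764 at unadjusted p below 0.05). The Cort call was lost without T54S1, T54S2, T6N2, T6N3, T6N4 or J76N2, and that of Cryl1 without any 1 of the 3 T60 libraries or T12N1 or T12N5. Single libraries decided other counts: the T54 count was 643 without T54S4 and 2 without T6N3, and the T60 count 3 without T12N4 and 2 without T12N2 or T12N6. The T72 count was 4 without T0N8 and 2 without J70N2, and the T198 count 118 without J76S2, 3 without T6N3 and 2 without J76S1.

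At T66, 36 h after deprivation ended, 6 genes were higher and 5 lower than at ZT18. Of the 6, 4 belong to cholesterol biosynthesis: Idi1 (0.46, SE 0.10, adjusted p = 0.0249), Msmo1 (0.43, SE 0.09, adjusted p = 0.0228), Sqle, the squalene epoxidase gene (0.33, SE 0.06, adjusted p = 0.0184), and Sc5d (0.25). Scd1, a fatty acid desaturase gene, was higher too (0.28), and Cnot3 (-0.31) and Sf3a2 (-0.30) were lower. Of 21 cholesterol genes 15 were higher adjusted over the list alone, and the set was called with an estimated correlation (adjusted p = 0.0188, median 0.27). Oligodendrocyte markers had a median of 0.24 in the same comparison (3 higher adjusted over the list alone; adjusted p = 0.683 with an estimated correlation). With their score as a covariate, chosen after seeing the data, limma called 0 genes (890 at unadjusted p below 0.05) and the median of the cholesterol list was 0.24. Against the 2 batch 2 controls alone 20 of 21 list genes were higher, with a median of 0.29. Without T66 library T66S3, or without ZT18 library T18N7, 1 gene was called at T66, without T18N3 6, and without T18N8 19.

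**Figure D2:**
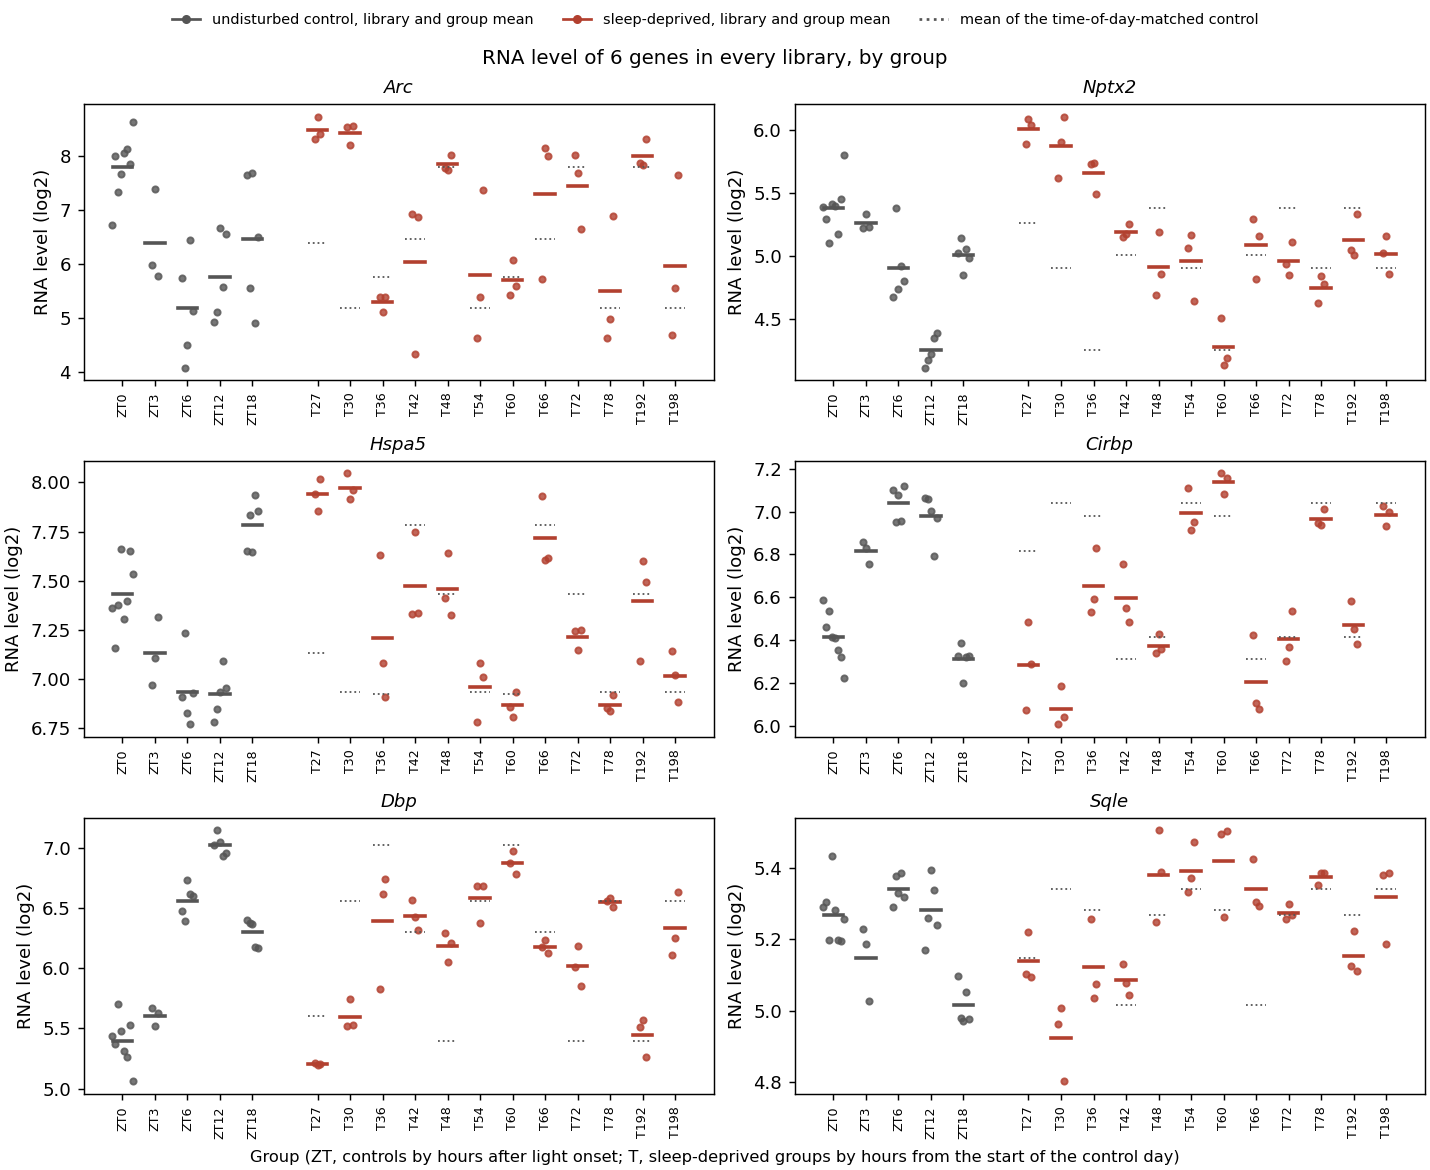
Level (log2 units, vertical axis) of Arc, Nptx2, Hspa5, Cirbp, Dbp and Sqle in each RNA library (points) by group along the horizontal axis, controls at ZT0 to ZT18 first and sleep-deprived groups T27 to T198 after them, with solid lines for group means and dotted lines for the mean of matched controls. Dbp at T30 lay between 5.52 and 5.75 in the 3 deprived animals and averaged 6.56 in ZT6 controls.

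**Figure D3:**
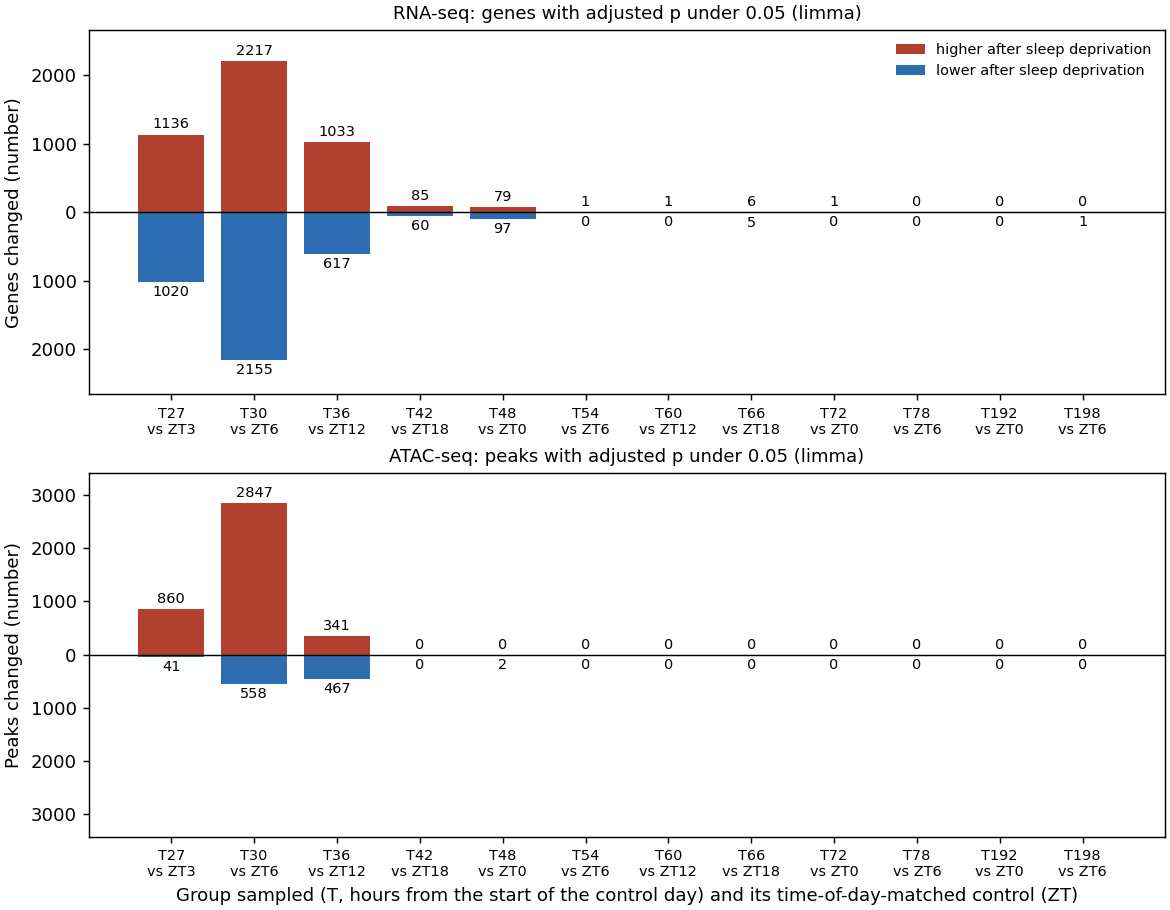
Number of genes (RNA-seq) and peaks (ATAC-seq) called higher (bars upward) and lower (bars downward) in sleep-deprived animals than in controls of the same time of day (limma, adjusted p below 0.05), for each of the 12 comparisons in order of time. Calls were most numerous at T30, with 4372 genes and 3405 peaks, and stood at 176 genes and 2 peaks at T48.

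The return of the 6 h response was followed over all later times. The 1737 genes higher at T30 against batch 1 controls had a median log2 change of 0.30 there, 0.19 at T27, 0.09 at T36, -0.04 at T42, -0.02 at T48, 0.04 at T54, -0.02 at T60 and -0.03 at T66. Between T72 and T198 their medians lay from -0.02 to 0.04. For the 1667 genes lower at T30 the medians were -0.29 at T30, -0.17 at T27, -0.07 at T36, 0.06 at T42, 0.01 at T48, -0.03 at T54, 0.04 at T60, 0.02 at T66, 0.01 at T72 and -0.04 at T198, and nearer to 0 than at T72 for T78 and T192. T54, T78 and T198 were set against the 2 batch 2 ZT6 controls, with a batch term, so that no ZT6 control of T30 was used again; T54 and T78 animals were of batch 1. The genes were chosen for passing at T30, which by itself enlarges their T30 medians relative to those of other times. Between the ZT0 controls labelled T24 and T0, all undisturbed, genes higher at T30 had a median of -0.02 and genes lower at T30 one of 0.02, and limma called 0 genes between these controls (621 at unadjusted p below 0.05).

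**Figure D4:**
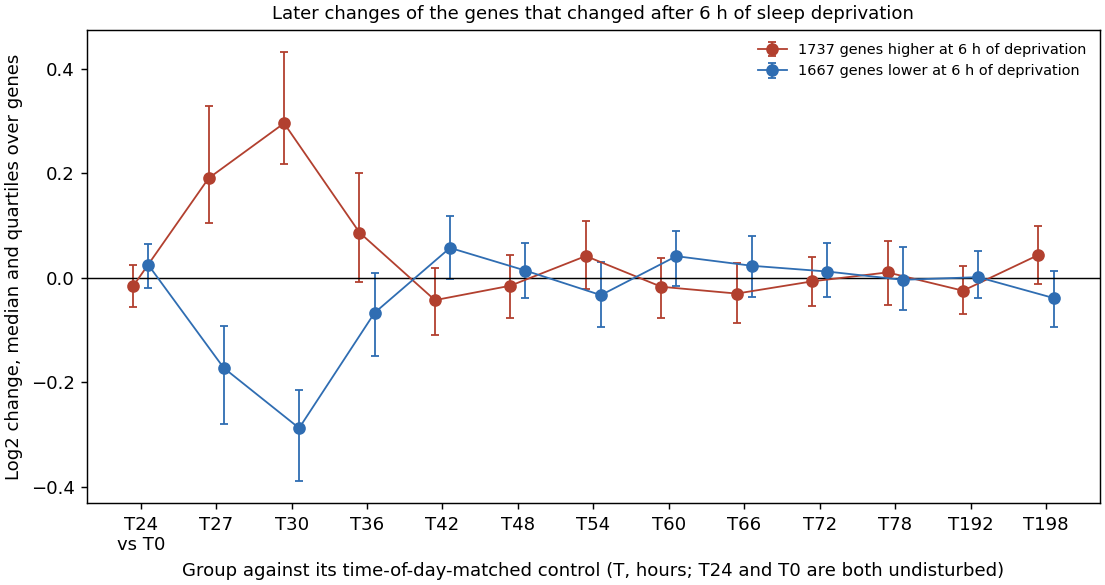
Median log2 change from controls of the same time of day (vertical axis) of the 1737 genes higher and the 1667 genes lower at T30, by group (horizontal axis; T24 against T0 compares undisturbed animals), with bars from the lower to the upper quartile over genes. T30 was compared with batch 1 ZT6 controls, and T54, T78 and T198 with the 2 batch 2 ZT6 controls. The medians moved from 0.30 and -0.29 at T30 to 0.09 and -0.07 at T36 and to -0.04 and 0.06 at T42.

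Whether the change from control varied over Day 2 was tested over T48, T54, T60 and T66 together, and 17 genes passed (2155 at unadjusted p below 0.05). Dbp varied over 0.94 log2 units (adjusted p = 0.00861). Tnnt2, a troponin gene, lay at -0.43 at T48 and 0.36 at T66, and Gja1, which encodes the astrocyte gap junction protein connexin 43, at -0.28 and 0.24 (adjusted p = 0.00468). Apln (0.62), Arntl (0.51), S1pr1 (0.49), Cnot3 (0.45), Cryl1 (0.44), Slc20a1 (0.27), Higd2a (0.23) and Fibcd1 (adjusted p = 3.28e-05) also passed. T60 and T66 animals were of batch 2 and T48 and T54 animals of batch 1, so this pattern relies on the batch term; without that term 132 genes passed. The count was 722 without T54S4, 31 without T66S2, 11 without T54S1 or T54S2, 6 without T48S1 and 5 without T48S4. Without a control it was 54 (T6N3), 27 (T0N1), 11 (T0N2, T18N7, T18N8 or J76N1) or 7 (T0N5).

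Open chromatin changed within 3 h, at first mostly by gain. At T27 860 peaks were more accessible than at ZT3 and 41 less, at T30 2847 were more accessible than at ZT6 and 558 less, and at T36 341 were more and 467 less accessible than at ZT12. The strongest gain at T27 was at chromosome 18, 83895119 to 83895856, between genes and 47473 bp from the gene model Gm31707, at 5.85-fold (log2 change 2.55, SE 0.30, adjusted p = 2.16e-08, n = 3 each). A peak 62232 bp from Trib1, a gene raised at T27, gained 2.08 log2 units (chromosome 15, 59719332 to 59719687, SE 0.38, adjusted p = 0.00164). Peaks inside Arhgef3 (-1.63) and Zfp316 (-1.61) lost accessibility. At T30 a peak 33846 bp from Cd109 gained 2.06 log2 units (chromosome 9, 78750107 to 78750740, SE 0.28, adjusted p = 1.33e-06). Another between genes on chromosome 17, 75936448 to 75937368, gained 1.89 (SE 0.24, adjusted p = 1.14e-07). Peaks inside Rgs7 (-1.54), Sipa1l3 (-1.53), Ddx39b (-1.43) and Ano1 (-1.41) lost accessibility. At T36 changed peaks lay inside Clec12b (1.72), Fhit (-1.84) and Galntl6 (-1.66), 19887 bp from Jam3 (1.49, not called by edgeR) and 19529 bp from App (-1.70). Named peaks were those with the largest changes, and some had low signal in 1 of the groups compared. The Trib1 peak stood at 0.02 ± 0.46 at ZT3, that of Rgs7 at 0.14 ± 0.99 at T30 and that of Fhit at 0.42 ± 1.23 at T36 (SD, n = 3 each). The median level over all peaks was 2.31, and the Cd109 peak stood at 1.92 ± 0.24 at ZT6 (SD, n = 5).

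Some peaks nearest to clock or immediate early genes changed, with or without the RNA. At T30 a peak inside Dbp (chromosome 7, 45705981 to 45706185) lost 1.05 log2 units (log2 change -1.05, SE 0.25, adjusted p = 0.00812) while its RNA fell, and a peak inside Ciart was lower (-0.47). Peaks inside Homer1 (1.19), Nfil3 (1.03) and Clock (0.61), whose RNA rose, were higher. RNA did not pass where a peak 3978 bp from Cry2 was lower at T30 (-0.93, RNA 0.10) and one inside Rora higher at T36 (0.84, RNA -0.09). A peak inside Msmo1 gained accessibility at T27 (1.16), T30 (0.94) and T36 (0.99), although Msmo1 RNA fell at T30 and did not pass at T27 (0.16) or T36 (-0.14). At T36 a peak 37228 bp from Nptx2 gained 1.02 log2 units (adjusted p = 0.0471).

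Of the peaks gained at T27 and T30, 57.4% and 50.8% lay inside a gene, against 67.0% of all peaks. Of those gained and lost at T36, 63.6% and 42.8% did. These differences were not tested. Of the 860 peaks gained at T27, 84.3% were also more accessible at ZT18 than at ZT6 in undisturbed controls, against 49.4% of all peaks, with no library in common. So were 73.0% of the 467 peaks lost at T36. The median change of the 860 peaks gained at T27 was 1.12 at T27, 0.79 at T30, 0.32 at T36, 0.06 at T42 and 0.05 at T48. It was 0.18 at T54 and 0.14 at T198, and lay from -0.08 (T192) to 0.00 (T78) at the other later times. These peaks were chosen for passing at T27, which by itself enlarges their T27 median relative to those of other times, T30 included. Peaks gained at T27 and T30 overlapped in 443 cases where independent lists would share 18.7, and those gained at T30 and T36 in 89 where 7.43 would be shared. The change from control differed between T36 and T30 in 460 peaks (96 upward, 364 downward) and between T30 and T27 in 0 (limma, 5678 at unadjusted p below 0.05).

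From T42 on, limma called 2 peaks, both less accessible at T48 (7100 peaks at unadjusted p below 0.05): one 23850 bp from Gm36859 (-1.18) and one 10860 bp from Rdh19 (-1.14; adjusted p = 0.0240 each). The first call was lost without T48S3, T48S4, T0N1, T0N3 or T0N5 and the second without T48S4, T0N1 or T0N3. In undisturbed controls 1823 peaks varied with time of day, highest most often at ZT12 (738) and ZT0 (657). The widest range was inside Hcn3, a pacemaker channel gene (1.86 log2 units between ZT6 and ZT3). That peak stood at 2.03 ± 0.74 at ZT6 (SD, n = 5) and at a low 0.25 ± 0.44 at ZT3 (SD, n = 3). In batch 1 alone 64 peaks varied. edgeR on recovered reads, chosen after seeing the data, called 1446 peaks at T27, 2610 at T30, 359 at T36, 0 at T48 and 1478 for time of day. Own-batch controls gave 975 peaks at T27, 3319 at T30 and 625 at T36. edgeR too called 0 peaks at the other times from T42 on. Peaks at unadjusted p below 0.05 by limma and by edgeR were 5527 and 5152 at T42, 11104 and 8680 at T54, 2804 and 4910 at T60, and 1771 and 6554 at T66. They were 6401 and 4704 at T72, 7669 and 5786 at T78, 4241 and 5123 at T192, and 8715 and 9628 at T198, where chance alone gives about 6536 of 130727. For the time-of-day pattern of Day 2 both called 0 peaks (4795 and 6356), and between the controls labelled T24 and T0 likewise (9914 and 5921).

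Single libraries moved the peak counts. Without T27S5, T27S3, T3N4 or T3N2 the T27 count was 90, 111, 266 or 549. Without T30S1, T30S4 or T6N4 the T30 count was 1209, 1238 or 1470. Without T36S2, T36S1, T12N1 or T12N4 the T36 count was 153, 198, 250 or 308, and without T12N1, T12N6 or T12N4 the time-of-day count was 960, 1071 or 1141.

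RNA and accessibility near the same genes were compared at T27, T30 and T36, in 6 tests adjusted together. At T36, 37 of 202 gained peaks (18.3%) had a nearest gene whose RNA rose, against 11.0% of all peaks (Fisher's exact test over peaks, two-sided p = 0.00219, adjusted p = 0.0131); neighbouring peaks are not independent. For peaks gained at T30 the share was 277 of 1402 (19.8% against 19.3%, p = 0.633, adjusted p = 0.633, Fisher's exact test), and at T27 48 of 474 (10.1% against 8.59%, p = 0.218, adjusted p = 0.436, Fisher's exact test). Shares of lost peaks near genes that fell were 18.8% against 15.5% at T30 (p = 0.0868, adjusted p = 0.261) and 5.14% against 4.41% at T36 (p = 0.614, adjusted p = 0.633, Fisher's exact test). At T27, with 41 lost peaks, the 1000 peaks with the smallest p among those that went down were taken instead, and the share was 8.29% against 7.49% (p = 0.411, adjusted p = 0.617, Fisher's exact test). Over all peaks, the median accessibility change at T36 was 0.04 near genes whose RNA rose, 0.01 near unchanged and -0.02 near lower genes; at T30 it was -0.04, -0.04 and -0.05, and at T27 -0.01, -0.02 and -0.04.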

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

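Tests chosen only after results were seen were those of the marker score at T48, both tests of Ttr, the fits with a marker score as a covariate, the permutations of r at T66 with its r for T30, and all counts over other splits of the libraries.

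T48 differed from ZT0 controls in 176 genes, with both clock genes and markers of thalamus or hippocampus among them. The mean score of the 7 measured thalamic and hippocampal markers was 0.27 log2 units higher at T48 (exact permutation p = 0.00606, two-sided, the smallest that 165 splits allow), with the lowest T48 library at 0.144 and the highest ZT0 library at 0.0691. The score is made of the markers whose rise prompted it, so it decides nothing about tissue from next to the cortex, which stays open for marker genes such as Fibcd1 (mean levels 2.75 log2 units at T48 and 1.84 at ZT0) and Tcf7l2 (2.51 and 1.90). Wfs1, the most abundant of these 3, moved less (5.65 and 5.45), and Fibcd1 stayed called with the score as a covariate although it is part of it (0.77, SE 0.12, adjusted p = 0.000301, against 0.91 before). Outside T48 the highest score was 0.309, in ZT3 control T3N2. With the score as a covariate, 4 of the 6 called clock genes stayed called (Dbp 0.87, SE 0.14), with 147 genes called in all. That fit cannot decide about such tissue for the clock genes, since Fibcd1, part of the score, stayed called in it as well. Batch is argued against for the clock genes, since 5 of 6 stayed called against batch 1 controls alone (Dbp 0.88, SE 0.13). Those controls included the merged column of T0N5, which also holds a batch 2 library, so they were not wholly of batch 1. An effect of deprivation on clock gene levels a day after it began stays open as a hypothesis.

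Ttr at T27 differed from ZT3 by -3.22 log2 units (SE 0.78), with ZT3 libraries at 7.54 (T3N2), 4.66 and 2.95, at most 5.04 in any other library, and T27 libraries averaging 1.83. Choroid plexus tissue in T3N2 is a candidate cause: without that library Ttr (-1.97, SE 0.78, adjusted p = 0.0968) and Kl (-0.10, adjusted p = 0.708) were no longer called, while 1 of the 3 measured markers, Enpp2 (-0.18, SE 0.06, adjusted p = 0.0277), still was. That source cannot be told apart from other causes, because 3 of 10 listed markers are in the table, Enpp2 is abundant in all libraries (7.38 at ZT3), and another ZT3 library carried a raised choroid score as well (0.92 in T3N3). At T30 Ttr differed from ZT6 controls by -0.22 (SE 0.71, adjusted p = 0.851), which argues against a fall in deprived animals as large as -3.22. With that SE a smaller fall stays open, and Enpp2 was called lower at T30 too (-0.18, limma adjusted p = 0.00508).

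Cholesterol biosynthesis genes were higher at T66 than at ZT18, with a median of 0.27 over 21 genes and 4 called. Batch as the cause is argued against by a median of 0.289 against the 2 batch 2 controls alone, with 20 of 21 genes higher, and by T60, also of batch 2, where the median was 0.07. A larger oligodendrocyte share as the whole cause is argued against by a median of 0.238 with the oligodendrocyte score as a covariate, though the set was not tested again. So it is by T48, where oligodendrocyte markers stood at 0.24 and cholesterol genes at -0.01. The single-gene calls did end with that covariate, as estimates became smaller while SE stayed about as large (Sqle from 0.33, SE 0.06, to 0.29, SE 0.07, adjusted p = 0.114, Idi1 from 0.46 to 0.38, both SE 0.10, adjusted p = 0.233, Msmo1 from 0.43 to 0.38, adjusted p = 0.137, Sc5d from 0.25 to 0.22, adjusted p = 0.114). Mean cholesterol scores of T66 libraries followed their oligodendrocyte scores (0.11 with 0.36 in T66S2, 0.05 with 0.09 in T66S3, 0.01 with -0.05 in T66S5). All lay above the highest ZT18 cholesterol score (-0.06 with -0.01 in T18N2). A partial contribution stays open. A more rest-like state of T66 animals, the biological explanation tested, needed a negative Pearson r with the changes during deprivation. Across 13821 other genes r was 0.135 with the T27 change, a value within what other splits of the T66 and ZT18 libraries give (0.146 from group means, exact permutation p = 0.0893, two-sided, 56 splits), and -0.0756 with the T30 change (-0.0618 from group means, exact permutation p = 0.446). Genes higher at T30 had a median of -0.03 at T66 and genes lower at T30 one of 0.02, so these values point both ways and such a state cannot be told apart from others. Other effects of deprivation on sterol synthesis stay open and were not tested.

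The change from control differed between T30 and T27 in 1 gene, Sorcs3. Between T36 and T30 it differed in 1573 genes and in 460 peaks, as a test of the difference itself. The change from control varied over the times of Day 2 in 17 genes. Among ZT6 controls, T6N3 lay far from the others in Ciart (4.69, others 5.25 to 5.41) and J76N2 in Erdr1 (6.08, others 7.03 to 7.33); chance marks about 1 in 20 groups, and 2 of 48 groups tested were marked.

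Counts of genes were set against other splits of the same libraries. At T30 1 of 56 splits, the real one, gave as many genes (4372, highest other 2703), at T36 1 of 56 (1650, 454), at T42 1 of 56 (145, 3) and at T48 1 of 100 (176, 9). No other split tried gave as many at these times. Each share was taken alone, without adjustment over the counts made, and these splits exchange libraries across batches, under a batch term. They therefore do not exclude chance by themselves. Within batch 1, where the T30, T36 and T42 groups meet 3 controls each, 10 splits are too few. At T48, with 4 controls, the merged column of T0N5 among them, 1 of 35 gave as many (48, highest other 20). For time of day too, no other split tried gave as many genes (1 of 100, 5630, highest other 1522), again across batches. At T66 (2 of 56; 11, 57) and for the Day 2 pattern (2 of 100; 17, 156) the shares were under 0.05 before any adjustment over the many counts made, but another split called several times as many genes. These counts therefore say less about chance, the more so as limma called 0 genes at T66 against batch 2 controls alone (950 at unadjusted p below 0.05), and as leaving out 1 library gave 1 (without T66S3 or T18N7) to 19 (without T18N8) at T66 and 5 (without T48S4) to 722 (without T54S4) for Day 2. At T27 the 10 splits were too few for a share under 0.05 (2156, highest other 0). Chance could not be excluded at T54 (12 of 56 splits; 1, 1911), T60 (3 of 56; 1, 1), T72 (7 of 100; 1, 1) and T198 (9 of 56; 1, 61). Where limma called 0 genes every split gives as many by definition, so these counts decide nothing about chance: T78 (56 of 56; highest other 4; 838 at unadjusted p below 0.05), T192 (100 of 100; 9; 1039) and the controls labelled T24 against T0 (35 of 35; 3; 621). Splits that called many times the real count point to a structure of the libraries apart from their groups. At T54 the split with 1911 genes joined ZT6 control T6N3 with T54S1 and T54S2, away from T54S4, and at T198 the one with 61 joined T6N3 with J76S1 and J76S3; against batch 2 controls alone limma called 0 genes at T198 (764 at unadjusted p below 0.05). At T36 the highest other split was that of the batch 1 ZT12 controls, T12N1, T12N2 and T12N4, against all others; against batch 1 controls alone 1133 genes were called.

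Peak counts were treated in the same way. As many peaks came from 1 of 56 splits at T30 (3405, highest other 1031), 1 of 56 at T36 (808, 27, again from the batch 1 ZT12 controls, with 625 against batch 1 controls alone) and 1 of 40 for time of day (1823, 129), the real one each time. These shares too were taken alone and in splits across batches, so they do not exclude chance by themselves. Within the batch, 3 batch 1 controls at T30 and T36 leave too few splits. At T27 the 10 splits were too few (901, highest other 1). Chance could not be excluded at T48 either (13 of 30 splits, 2, highest other 59). Where limma and edgeR both called 0, every split again gives as many, and the splits decide nothing. Those are given with the highest other count and the counts at unadjusted p below 0.05 by limma and edgeR: T42 (30 of 30 splits, 2, 5527, 5152), T54 (30 of 30, 199, 11104, 8680), T60 (30 of 30, 1, 2804, 4910), T72 (30 of 30, 2101, 6401, 4704), T78 (30 of 30, 3, 7669, 5786), T192 (30 of 30, 3407, 4241, 5123), T198 (30 of 30, 66, 8715, 9628) and the controls labelled T24 against T0 (35 of 35, 162, 9914, 5921). The split with 3407 peaks set ZT0 controls T0N5, T0N8 and T0N9 apart and that with 2101 set T0N5 and T0N9 apart with T72S3, which again points to a structure among ZT0 and T72 libraries, not along batch. The libraries set apart were among the shallowest (T0N8 and T0N9 2.31 M reads in peaks each, T72S3 2.60 M, T0N5 2.80 M; the other ZT0 and T72 libraries compared 3.12 M to 7.37 M), and whether depth is the source was not tested.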

How the results depend on the processing

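Chosen after seeing the data were the tests with edgeR, with the merged RNA column left out, with each ZT0 control (for Day 2 also each ZT6, ZT12 and ZT18 control) left out in turn, with a marker score as a covariate and with peaks inside genes only. Of 294 alternative results, 223 were rated the same as the original and 71 were not. Counts, those of lists called included, were rated the same within 1.5 times the original. Medians of the T30 genes were rated by sign, except that very small ones were always rated the same. Correlations were rated by the size of their shift, and that of T27 was 0.521 with and without a batch term. Some of the 223 ratings were thus fixed beforehand. Shares of peaks near changed genes were rated by whether p stayed on the same side of 0.05 (Fisher's exact test). No named gene or peak reversed, which says little, as all of them had been chosen for passing in the main comparison. In RNA 2763 values kept their call under the alternatives and 187 lost it (2789 and 467 when 1 library was left out), in ATAC 336 and 18 (238 and 48). RNA counts at T27, T30 and T36 stayed within 1.5 times under every alternative run except leaving out T36S1. Where a count moved, the cause was not tested, unless fewer libraries or genes explain it by construction. Counts in brackets after a 0 are those at unadjusted p below 0.05. RNA values had been adjusted for batch before deposit, so leaving out the batch term does not free them of batch adjustment. Without a batch term RNA calls were 238 at T42, 318 at T48, 4 at T54, 11 at T60, 38 at T66, 5 at T72, 49 at T198 and 132 for the Day 2 pattern, and ATAC calls 5 at T48 and 8 at T198. In the upper 75% of genes by level RNA calls were 106 at T48, 5 at T60, 2 at T72, 0 (1034) at T198 and 11 for Day 2. Quantile normalization gave 3 genes at T54, 2 at T60, 2 at T72 and 1 peak at T66. With a replicate block, although the numbers do not pair samples, limma called 84 genes at T42, 0 (1333) at T66 and 0 (1111) at T72, and 578 peaks at T27 and 0 (7066) at T48. Without the merged ZT0 column, RNA calls were 109 at T48, 0 (1481) at T54, 0 (934) at T72, 4 at T198 and 7 for Day 2. With only the libraries of the 2 groups compared, which estimates each spread from fewer libraries, they were 39 at T42, 0 (855) at T54, 0 (2285) at T60, 0 (1413) at T66, 2 at T72 and 0 (1243) at T198, and ATAC calls 2663 at T27, 1431 at T36, 0 (6213) at T48, 1 at T60 and 1 at T78. With controls of the own batch alone RNA calls were 40 at T42, 48 at T48, 0 (1285) at T60, 0 (950) at T66, 0 (964) at T72 and 0 (764) at T198, and ATAC calls 0 (7302) at T48 and 13 at T54. Time of day in batch 1 alone gave 2949 genes and 64 peaks, and a 24 h cosine 1204 peaks. A pseudocount 10 times smaller gave 4 peaks at T48 and 3 between the controls labelled T24 and T0, and one 10 times larger 1576 at T27 and 0 (7239) at T48. edgeR called 1446 peaks at T27, 359 at T36 and 0 (6884) at T48. With the oligodendrocyte score as a covariate limma called 0 (890) genes at T66. The correlation of the T30 change with ZT18 minus ZT6 was 0.753 over all libraries with shared controls left in and no batch term, against 0.484; sharing raises r by construction, but more libraries entered too, and the shares of each were not tested. With an estimated correlation the lists called fell from 11 to 2 at T36, 3 to 1 at T42, 8 to 0 at T48, 5 to 0 at T54, 4 to 0 at T60, 5 to 1 at T66, 7 to 0 at T72, 5 to 0 at T78, 7 to 0 at T192, 4 to 0 at T198 and 9 to 0 for ZT18 against ZT6; at T27 and T30 6 of 9 held. Leaving out 1 library at a time gave RNA counts of 1460 to 1845 at T27, 3215 to 4445 at T30, 812 (without T36S1) to 1605 at T36, 48 to 149 at T42, 70 (without T48S4) to 189 (without T0N9) at T48, 0 to 643 at T54 (643 without T54S4, 0 to 2 otherwise), 0 to 3 at T60, 1 to 19 at T66, 0 to 4 at T72, 0 to 0 at T78, 0 to 2 at T192, 1 to 118 at T198 (118 without J76S2, 2 without J76S1, 3 without T6N3), 5098 to 5768 for time of day and 5 to 722 for Day 2 (722 without T54S4). ATAC counts were 90 (without T27S5) to 690 at T27, 1209 (without T30S1) to 3630 at T30, 153 (without T36S2) to 925 at T36, 0 to 2 at T42, 0 to 5 at T48, 0 to 1 at T54, T72 and T78, 0 to 0 at T60, T66, T192 and Day 2, 0 to 21 at T198 (21 without J76S1) and 960 (without T12N1) to 2199 for time of day. At this depth and group size ATAC could miss changes: 10% of simulated changes of 0.5 log2 units and 48% of changes of 1 were recovered at T30, so peaks that were not called may still have changed. edgeR called 1446 peaks where limma called 901 at T27, but fewer at T30 (2610 against 3405) and T36 (359 against 808). Not run were a distance limit to transcription starts, and for RNA the repeat library and other pseudocounts.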

Other observations

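Chosen after results were seen were the tests of an opposite swing at T42 and of the clock gene slope at later light onsets.

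Several lists shifted at later times with at most 1 of their genes called in these comparisons, and none of these shifts held with an estimated correlation (camera; adjusted p in brackets, estimated correlation). Oligodendrocyte markers had a median log2 change of 0.24 at T48 (0.505), 0.17 at T60 (0.766), 0.24 at T66 (0.683), -0.26 at T72 (0.235) and -0.23 at T192 (0.675), with 8 of 12 lower at T72 and 7 of 12 at T192 adjusted over the list alone. At T60 oxidative phosphorylation genes stood at 0.10 (0.475), cytosolic ribosomal protein genes at 0.07 (0.766) and clock genes at -0.11 (0.525). At T198 ribosomal protein genes stood at 0.08 (0.860). At T54 neuropeptide genes had a median of 0.21, with 7 of 13 higher adjusted over the list alone (0.661), and immediate early genes one of 0.29 (0.908). At T72 clock genes had a median of 0.17, with 8 of 21 higher and 2 lower adjusted over the list alone (0.235).

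Activity-induced genes varied widely among libraries of 1 group. Arc stood at 7.38 in T54S4 against 4.63 and 5.40 in the other T54 libraries, at 6.89 in T78S4 against 4.64 and 4.99, and at 7.64 in J76S3 of T198 against 4.69 and 5.57, while ZT6 controls ranged from 4.09 to 6.45 and ZT18 controls from 4.92 to 7.68. Fos showed the same libraries apart: 5.53 in T54S4 against 3.15 and 3.37, 5.04 in T78S4 against at most 2.44, and 5.44 in J76S3 against 2.85 and 3.98. Choroid plexus scores were highest in T3N2 and T18N8, followed by T3N3 (0.92) and T42S6 (0.84).

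The repeat ATAC library T0N3_2 was left out of the main comparisons and used only in the alternative that included it. It correlated at 0.890 (Pearson r over peaks) with the other library of its animal, T0N3, and at 0.917 with J70N2, and at 0.832 to 0.905 with the other ZT0 libraries. Its identity was not tested further.

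Genes higher at T30 lay somewhat lower at T42 and those lower at T30 somewhat higher, and a candidate explanation is an opposite swing in the first recovery night. The median of the 1737 higher genes minus that of the 1667 lower ones differed from controls by -0.10 at T42 (exact permutation p = 0.0179, two-sided, the smallest that 56 splits allow; adjusted p = 0.107 over 6 comparisons). The difference thus did not pass after adjustment, and the hypothesis stays open. The other comparisons gave p = 0.461 at T48, p = 0.107 at T60, p = 0.161 at T66, p = 0.606 at T72 and p = 0.588 at T192 (exact permutation tests).

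A smaller daily swing of clock genes after deprivation may underlie the changes at light onset. Over the 21 clock genes, the T48 change had a slope of 0.397 on the control difference ZT12 minus ZT0 (Pearson r = 0.929 across genes, which are not independent replicates; exact permutation p = 0.0286, two-sided, the smallest that 35 splits allow; adjusted p = 0.0429 over T48, T72 and T192), so genes that are low at ZT0 lay higher. The slope was 0.327 at T72 (r = 0.877, same exact p and adjusted p) and 0.0570 at T192 (exact p = 0.2). At ZT12 the slope was -0.531 at T36 (exact p = 0.1, the smallest that 20 splits allow) and -0.107 at T60 (exact p = 0.2, where 10 splits allow 0.1). Of these 5 slopes, 3 were adjusted together. Library T36S1 stood apart in clock genes, with a mean score of -0.14 against 0.04 and 0.10 in the other T36 libraries. The T36 slope was not computed without it. The control difference came from ZT0 animals labelled T0, and T48, T72 and T192 shared the same 4 animals labelled T24 as controls, so the slopes are not independent of each other. T48 and T72 animals were of batch 1 and T192 animals of batch 2, while 2 of the 4 controls came from each batch, so the 35 splits mix batches. Within the batch of the deprived animals, against 2 controls each, the slope was 0.342 at T48 and 0.275 at T72 (exact p = 0.1 each, the smallest that 10 splits allow) and 0.0376 at T192 (exact p = 0.5). For T48 and T72, 1 of the 2 controls was the merged column of T0N5, which also holds a batch 2 library. The larger slopes, T36 included, fell in batch 1 groups and the smaller ones in batch 2 groups, so a change with time since deprivation cannot be told apart from batch. A shift in phase in place of a smaller swing was not tested.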
